A study of Mus musculus with 46 samples.

How the data were processed

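Chromatin immunoprecipitation followed by sequencing was made from livers of individual male mice with antibodies to RXRa, CEBPa and CEBPb, and 4 input controls were sequenced without immunoprecipitation, per the labels' protocols. Reads were processed with Bowtie2 2.3.2 and MACS2 on the assembly mm9, per the submitters' processing notes; the version of MACS2 and its settings are not given in the sources used here. The authors deposited 1 list of peaks per library, so peaks were called on each liver separately and not on pooled livers. Each deposited list gives the chromosome, start, end and name of a peak and no other value. Starts counted from 0 were raised by 1 for every position printed. The last peak on chromosome 1 ends at 197111763, beyond the last gene end of 195291439 in a table of the later assembly GRCm38, so that table was not used. Positions were not converted, and regions carry no gene names.

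Because the lists carry no fold enrichment, score, p-value, q-value or summit, peaks could not be ranked or filtered by strength. The width percentile of a peak within its own list was used in their place, a choice made after the lists were seen. No read counts come with the lists, so the depth of each library is unknown, and no interval that needs it is given. A list can be longer because its library was deeper or more enriched, and a region without a peak may hold signal below the caller's threshold. Peak names are numbered, and 111 to 488 numbers per immunoprecipitated list (0.544% to 1.29%) are not used by any listed peak; the reason is not given in the sources used here. The narrowest peak per immunoprecipitated list was 178 to 226 bp wide. No 2 lists of a group looked like copies, since at most 0.0354% of peaks had the same start and end in 54 pairs.

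Libraries were grouped by factor, treatment and time from the labels. All groups of one comparison share a sequencing lane in the labels. The RXR libraries of both times share 1 lane, while the CEBP libraries of 3 h and 27 h lie on different flow cells and come from mice of different ages. Peaks that overlapped by at least 1 bp were merged into regions over the libraries of each comparison. The numbers of gained and lost regions were set against every other assignment of the same libraries to groups of the same sizes, in one-sided exact tests with Benjamini-Hochberg adjustment over 12 counts. With so few livers the adjusted p could not fall below 0.0571 for these counts, for list similarity and list length (6 tests each) or for call rates (60 tests), nor below 0.0381 for shared peaks (8 tests), so a missed adjusted threshold in the first 4 families shows nothing about an effect. Control regions had a peak in as many libraries as a gained region, but in libraries of both treatments. The similarity of lists was the mean Jaccard index of pairs within groups minus that between groups. List lengths were compared as log2 peak numbers in exact permutation tests over the 6 comparisons. Overlaps between factors in the same liver counted a peak as shared from 1 bp, with the other factor's peaks moved by 100 kb as the background. Overlaps of gained lists were tested with Fisher's exact test over regions called in both comparisons, and by reassigning livers for both lists at once, or within each time where the animals differ. The comparisons above were fixed before the data were examined. Added after the data were seen were the adjustment over 12 counts, the reassignment of livers for 2 gained lists, the control regions with their call rates, the wider regions, RXR over both times together, its call rates without each liver and the ratio of CEBPb to CEBPa peaks.

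The regions named in the text were taken, for each comparison and direction, from the 10 with the highest mean width percentile, in that order as far as length allowed; regions shared by 2 lists were taken in the same order. The regions on chromosome 3 at 113022802 and on chromosome 12 at 14216580 were singled out after their values were seen. The rule also named every window of 200 kb with at least 3 gained or 3 lost regions, and there was none. Lists of genes fixed in advance, genomic context and sequence motifs need an annotation or sequence of mm9 and were not analysed here. The functions were tested on simulated lists in which 200 regions per comparison were called with a probability of 95% in one group and 5% in the other. They recovered 64.5% of these for RXR at 27 h and 67% for CEBPb at 27 h, none on the wrong side, each as many as the simulated calls allowed. Among the unchanged simulated regions, 92 and 196 met the definition of gained or lost by chance. For CEBPa at 27 h 127 did. At 3 h the numbers were 459 for RXR, 534 for CEBPa and 368 for CEBPb, each above the 256, 497 and 271 observed. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

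Alternatives were lists without peaks that overlap an input peak, regions in all but at most 1 library, exchange of livers only within the same number, each library left out, and sharing from 50% of the width. Added after the lists were seen were equal-length lists of the widest or of randomly drawn peaks (mean of 20 draws), and windows of 100 bp on either side of each peak's midpoint in place of summits.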

Results

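The series measured where 3 transcription factors bound chromatin in the liver of adult male CD-1 mice after a single injection of TCPOBOP, a ligand that activates the nuclear receptor CAR, or of vehicle (DMSO in corn oil). RXRa, labelled RXR here, is the nuclear receptor that pairs with CAR and with many other nuclear receptors, and CEBPa and CEBPb are bZIP transcription factors of the liver. Livers were collected 3 h or 27 h after the injection of 3 mg/kg TCPOBOP or of vehicle. Each of the 46 libraries came from 1 liver and is represented by the list of peaks called in it. There were 3 livers per treatment and factor at 3 h, 4 at 27 h, and 4 input controls of chromatin without immunoprecipitation, 2 from each treatment. At 27 h all 3 factors were measured in the same 8 livers. At 3 h both CEBP factors were measured in the same 6 livers, and RXR in 6 others.

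The 42 immunoprecipitated libraries held 11899 to 55513 peaks each, and the input controls held 1480, 224, 42 and 7. The number of reads behind each list is unknown. The question the design asks is where binding of each factor differs between TCPOBOP and vehicle livers at each time. Regions were formed by merging overlapping peaks over the libraries of a comparison. A region was counted as gained when every TCPOBOP library and no vehicle library had a peak in it, and as lost in the reverse case. Positions are on the mouse assembly mm9, and no gene is named because no annotation of that assembly was used here.

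**Figure D1:**
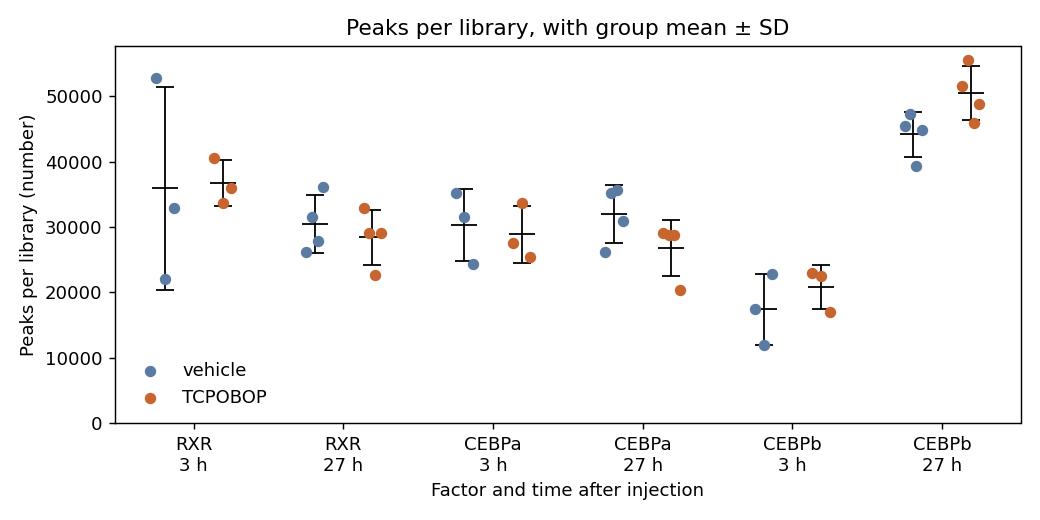
Number of peaks in each immunoprecipitated library (points), by factor and time in hours, with the mean and SD of each group in black; vehicle libraries are blue and TCPOBOP libraries orange. The 4 CEBPb lists of TCPOBOP livers at 27 h hold 45877 to 55513 peaks, the 4 of vehicle livers 39275 to 47279.

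At 27 h, CEBPb was called at 331 regions in all 4 TCPOBOP livers and in none of the 4 vehicle livers, and at 34 regions in the reverse pattern, out of 92566 regions. CEBPb peaks were common to all 8 livers at 23684 regions. The region with the widest gained peaks lay on chromosome 19 at 40301067 to 40301585, where RXR was called in all 8 livers of the same time. At chromosome 2, 27237124 to 27237649, CEBPb and RXR were each called in 4 TCPOBOP and 0 vehicle livers. The next gained region, on chromosome 10 at 98139566 to 98140039, had RXR peaks in 3 TCPOBOP and 0 vehicle livers. The lost region with the widest peaks lay on chromosome 16 at 64855873 to 64856494 and had no RXR peak in any library.

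The 331 gained CEBPb regions were more than any other assignment of the 8 libraries gave (highest 204, median 64; exact test, one-sided p = 0.0143, the smallest that 70 assignments allow). Over the 12 counts of gained and lost regions the exact test allows no adjusted p below 0.0571 whatever the data, so its adjusted p of 0.171 does not decide on these regions. The same bound holds for the adjusted p of list similarity, list length and call rates below. The 34 lost regions were fewer than the 67 of the median assignment (exact p = 0.886). Pairs of CEBPb lists from the same treatment shared slightly more regions than pairs from different treatments, with Jaccard indices of 0.584 and 0.572 (exact one-sided p = 0.0286, adjusted p = 0.0857). The unadjusted call was lost without any 1 of the 4 TCPOBOP livers (exact p of 0.0571 to 0.114). With all lists shortened to their 39275 widest peaks, an alternative chosen after the data were seen, 152 regions were gained and 75 lost (exact one-sided p = 0.0143 and 0.143).

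The CEBPb lists of TCPOBOP livers at 27 h were longer, at 50457 ± 4099 peaks (SD, n = 4) against 44201 ± 3448 (SD, n = 4) in vehicle livers, a ratio of 1.14. This difference was not past the threshold in the exact permutation test (two-sided p = 0.0571, adjusted p = 0.343).

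**Figure D2:**
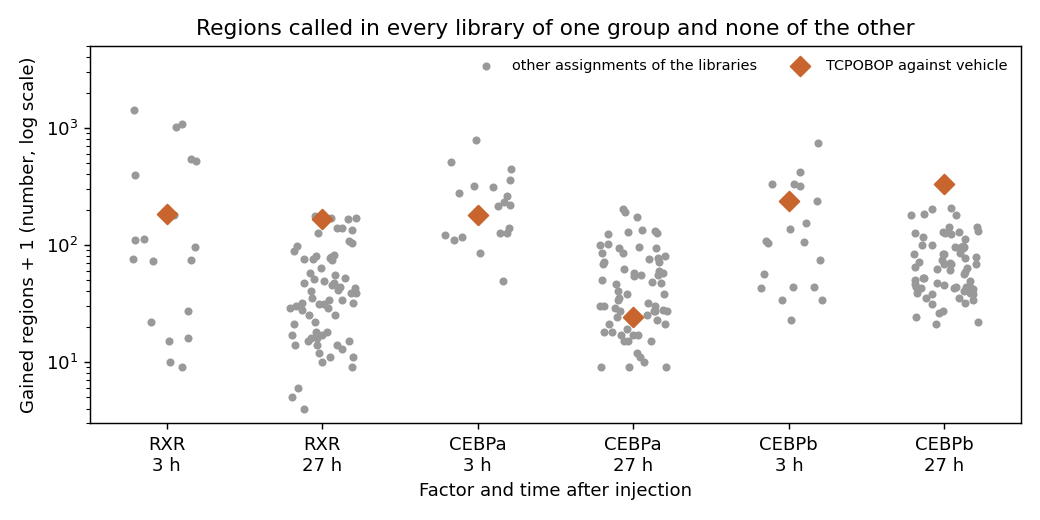
Number of gained regions plus 1 (log scale) for TCPOBOP against vehicle (diamonds) and for the other assignments of the same libraries to 2 groups of the same sizes (grey points), by factor and time in hours. For CEBPb at 27 h the 331 gained regions lie above all other assignments, of which the highest gives 204.

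RXR gained 164 regions at 27 h and lost 134, out of 57725, while 13441 regions had an RXR peak in all 8 livers. The gained region on chromosome 6 at 85877526 to 85878196 had an RXR peak in 4 TCPOBOP and 0 vehicle livers at 27 h, in 3 and 0 livers at 3 h, and no CEBP peak in any library. At chromosome 6, 119427764 to 119428323, the RXR peak appeared at a site where CEBPb was called in all 8 livers of 27 h. At chromosome 6, 131333724 to 131334286, RXR and CEBPb were both gained, and neither had a peak there in any vehicle liver at 27 h. Among lost regions, chromosome 14 at 64162221 to 64163029 had the widest peaks, and chromosome 11 at 105835973 to 105836500 came next, both without any CEBP peak.

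Of the 70 assignments of the 8 RXR libraries, 5, the real one included, gave at least 164 gained regions (exact one-sided p = 0.0714, adjusted p = 0.286), and 8 gave at least 134 lost ones (p = 0.114 by the same exact test, adjusted p = 0.343). Among the wider regions, those with a mean width percentile of at least 50, 50 were gained and no other assignment gave more than 39 (exact one-sided p = 0.0143). With lists shortened to their 22619 widest peaks, 177 regions were gained and 92 lost, and no other assignment gave more than 92 gained regions (exact one-sided p = 0.0143 for gained and 0.0286 for lost regions). Both alternatives were chosen after the data were seen, and their p-values are not adjusted. When all but at most 1 library of a group sufficed, more RXR regions were lost than gained. RXR lists from the same treatment were also more alike than lists from different treatments, with Jaccard indices of 0.570 and 0.556 (exact one-sided p = 0.0286, adjusted p = 0.0857). That unadjusted call was lost in 5 of the 8 cases of leaving out 1 liver (exact p of up to 0.114). RXR list lengths were 28401 ± 4257 (SD, n = 4) in TCPOBOP and 30418 ± 4426 (SD, n = 4) in vehicle livers (exact permutation p = 0.6, two-sided).

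CEBPa at 27 h gained 23 regions and lost 131, out of 63546, with 12936 called in all 8 livers. The gained region with the widest peaks, on chromosome 1 at 13193705 to 13194182, had CEBPb and RXR peaks in all 8 livers. The next, on chromosome 1 at 170973580 to 170973976, had RXR peaks in 2 TCPOBOP and 0 vehicle livers. At the lost region on chromosome 9, 86846977 to 86847339, CEBPb was called in 4 vehicle livers and 1 TCPOBOP liver. The lost region on chromosome 2 at 5743488 to 5743933 had RXR and CEBPb peaks in all 8 livers.

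With the full lists, neither CEBPa count at 27 h stood above the other assignments (exact one-sided p = 0.743 for gained and 0.0714 for lost regions). The TCPOBOP liver D4 had the shortest CEBPa list of this time, and without it 99 regions were gained in place of 23. Leaving out a library raises such a count by construction. With all lists shortened to their 20396 widest peaks, 52 regions were gained and 43 lost (exact one-sided p = 0.0286 and 0.2, unadjusted). With randomly drawn peaks the gained count had an exact p of 0.0571. CEBPa lists held 26776 ± 4255 peaks in TCPOBOP and 31984 ± 4436 in vehicle livers (SD, n = 4 each; exact permutation p = 0.2, two-sided).

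At 3 h after injection RXR gained 184 regions and lost 72, out of 64075, with 17352 called in all 6 livers. With lists of equal length most of that lead was gone, at 179 gained and 157 lost regions with the widest peaks and 431 and 421 with randomly drawn ones. It turned to more lost than gained regions when all but at most 1 library of a group sufficed. The gained region with the widest peaks was on chromosome 12 at 57155566 to 57156310, where at 27 h RXR was called in 1 TCPOBOP and 1 vehicle liver. The next, on chromosome 3 at 148581315 to 148582146, had RXR peaks in 4 TCPOBOP and 3 vehicle livers at 27 h. The lost region on chromosome 6 at 8366942 to 8367547 had an RXR peak in 2 TCPOBOP and 4 vehicle livers at 27 h.

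With 3 livers against 3, the one-sided exact test cannot go below p = 0.05, and 7 of the 20 assignments gave at least 184 gained RXR regions (p = 0.35). The vehicle liver A1 had 52727 RXR peaks, against 22117 and 32858 in the other vehicle livers, and without it 1720 regions were gained. Leaving out a library raises the count by construction. RXR lists held 36734 ± 3463 peaks in TCPOBOP and 35901 ± 15530 in vehicle livers at 3 h (SD, n = 3 each; exact permutation p = 0.7, two-sided, where 0.1 is the smallest possible). The treatment difference in RXR list length, as a log2 ratio, differed by -0.22 between 27 h and 3 h (exact permutation of the times over 14 libraries, two-sided p = 0.587).

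The CEBP factors at 3 h gave counts within those of other assignments. CEBPa gained 179 regions and lost 318 out of 56005, and CEBPb gained 238 and lost 33 out of 39887. For CEBPb the balance turned with lists of equal length, to 119 gained and 138 lost regions with the widest peaks and to 163 and 313 with randomly drawn ones. The lost CEBPa region on chromosome 6 at 52551750 to 52552472 had RXR peaks in every RXR library of both times. The one on chromosome 11 at 79361888 to 79362508 had CEBPa peaks in all 8 livers at 27 h. The gained CEBPb region on chromosome 2 at 58421371 to 58422006 had CEBPa and CEBPb peaks in all 8 livers at 27 h. The exact one-sided p was 0.6 for gained and 0.25 for lost CEBPa regions, and 0.3 and 0.95 for CEBPb. List lengths were 28860 ± 4302 and 30320 ± 5555 peaks for CEBPa in TCPOBOP and vehicle livers, and 20789 ± 3345 and 17386 ± 5425 for CEBPb (SD, n = 3 each; exact permutation p = 0.8 and 0.6, two-sided).

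Part of the RXR gain was seen at both times, in different animals. Of the regions that RXR gained at 27 h, 15 were also gained at 3 h, where lists of these sizes drawn independently would share 0.527 (Fisher's exact test, one-sided p = 8.43e-18, adjusted p = 5.90e-17 over 7 pairs of lists). With lists of equal length 9 were shared, against 0.667. Fisher's test treats regions as independent and equally likely to be gained, which they are not. When the libraries were reassigned within each time, none of the others among 1400 assignments gave more than 13 such regions, and the median was 0 (exact one-sided p = 0.000714, the smallest possible). Besides the chromosome 6 region at 85877526, the 15 regions included chromosome 16 at 44270889 to 44271387 with CEBPb peaks in all 8 livers of 27 h, and chromosome 5 at 129067017 to 129067425, without any CEBP peak. No region had an RXR peak in all 7 vehicle livers and in no TCPOBOP liver. When 6 of the 7 TCPOBOP livers sufficed, 42 regions were gained, and 21 of the 1400 assignments gave as many (highest 76). Without the vehicle liver A1, 43 regions were gained at both times, but such a count rises by construction with fewer libraries.

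Regions gained by RXR at 27 h were also called more often in TCPOBOP than in vehicle livers at 3 h, at 68.7% ± 9.80 of the 164 regions against 29.9% ± 25.8 (SD, n = 3 each). Control regions, which had an RXR peak in 4 of the 8 livers of 27 h but in a mix of both treatments, were called at 67.3% and 59.9%. The excess of 31.4 percentage points had the smallest p that 3 livers against 3 allow (exact permutation, two-sided p = 0.1). It was 18.2 points with lists of equal length. Without the vehicle liver A1, where 58.5% of the regions were called, the vehicle share was 15.5% and the excess 30 points. In the other direction, the 184 regions gained at 3 h were called at 43.9% ± 10.6 in TCPOBOP and 24.6% ± 6.78 in vehicle livers of 27 h (SD, n = 4 each). Their control regions were called at 28% and 32.6% (exact permutation of the excess, two-sided p = 0.0286). The rates of single livers at the 184 regions overlapped, at 31% to 56% in TCPOBOP and 17.4% to 33.7% in vehicle livers. Over the family of 60 such comparisons, chosen after the data were seen, the adjusted p of these results was 0.381 and 0.214, where no value below 0.0571 was possible. Regions lost by RXR at 27 h were called at 69.2% and 65.4% in TCPOBOP and vehicle livers at 3 h.

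**Figure D3:**
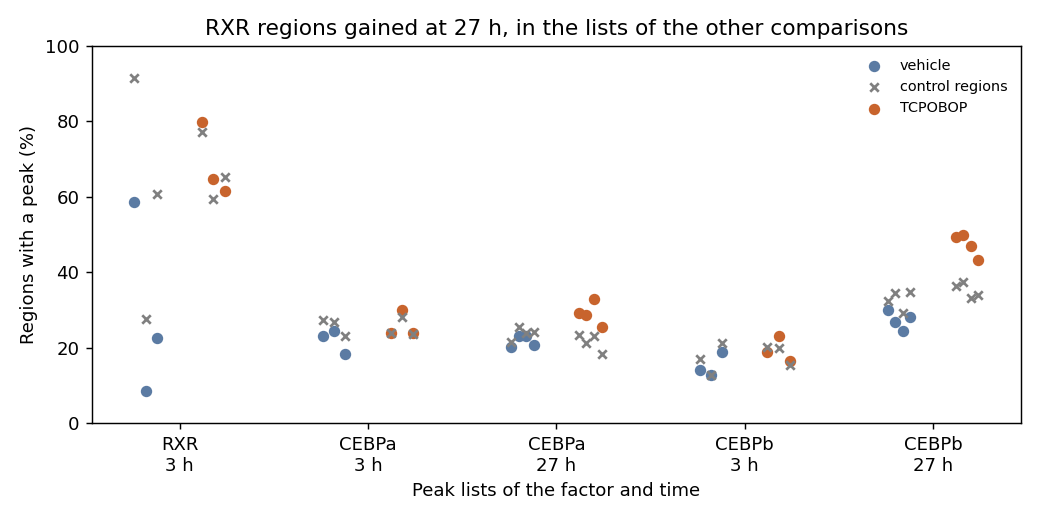
Share in percent of the 164 RXR regions gained at 27 h that hold a peak in each library of the other comparisons, for vehicle (blue) and TCPOBOP (orange) livers; crosses show the control regions in the same libraries. In the CEBPb lists of 27 h the 4 TCPOBOP libraries lie between 43.3% and 50%, the 4 vehicle libraries between 24.4% and 29.9%.

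At 27 h, where all factors were measured in the same livers, RXR and CEBPb had 9 gained regions in common, against 0.47 for independent lists (Fisher's exact test, one-sided p = 1.10e-09, adjusted p = 3.83e-09). No other assignment of the 8 livers, made for both factors at once, gave more than 3 (exact one-sided p = 0.0143). Besides chromosome 6 at 131333724, these 9 included chromosome 3 at 87925358 to 87926000, chromosome 2 at 27237172 to 27237592 and chromosome 7 at 97426125 to 97426519. CEBPb was called at 47.4% ± 3.05 of the 164 gained RXR regions in TCPOBOP livers and at 27.3% ± 2.3 in vehicle livers (SD, n = 4 each). CEBPb call rates at control regions were 35.2% and 32.7% (exact permutation of the excess, two-sided p = 0.0286, adjusted p = 0.214). RXR in turn was called at 23.7% ± 5.35 and 12.6% ± 2.47 of the 331 gained CEBPb regions in TCPOBOP and vehicle livers. Control regions had RXR at 12.3% and 12.9% (exact permutation of the excess, p = 0.0286, adjusted p = 0.214). CEBPa showed the same direction, at 29.1% ± 3.00 and 21.8% ± 1.60 of the gained RXR regions, with 21.5% and 23.8% at control regions. At the gained CEBPb regions, CEBPa was called at 16.9% ± 6.63 and 12.5% ± 4.30, with 12.5% and 19.9% at control regions (SD, n = 4 each). For each of these 2 CEBPa results, the exact permutation of the excess gave p = 0.0286 (two-sided, adjusted p = 0.214). At the gained CEBPb regions the CEBPa rates of single livers overlapped between treatments. The treatment difference was 4.46 points there and -7.44 at control regions, so most of that excess lay in the control regions. The regions were chosen in these same livers, so animal differences shared by 2 factors could raise each excess. The p-values of these call rates therefore do not measure treatment alone. In 3 h lists, from other animals, the excess at gained RXR regions was 2.73 points for CEBPb and 4.42 for CEBPa. At 27 h it was 17.6 and 9.53. At gained CEBPb regions the excess was 5.22 points for RXR and 2.28 for CEBPa at 3 h, against 11.7 and 11.9 at 27 h. These 3 h excesses had exact permutation p-values of 0.1 or 0.2 (two-sided). CEBPb itself was called at 3 h at 3.6% and 2.5% of its gained regions in TCPOBOP and vehicle livers. Control regions were called at 6.5% and 4.3%, an excess of -1.08 points (exact permutation, two-sided p = 0.3). The CEBPb lists of 3 h were much shorter than those of 27 h, which limits this comparison.

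**Figure D4:**
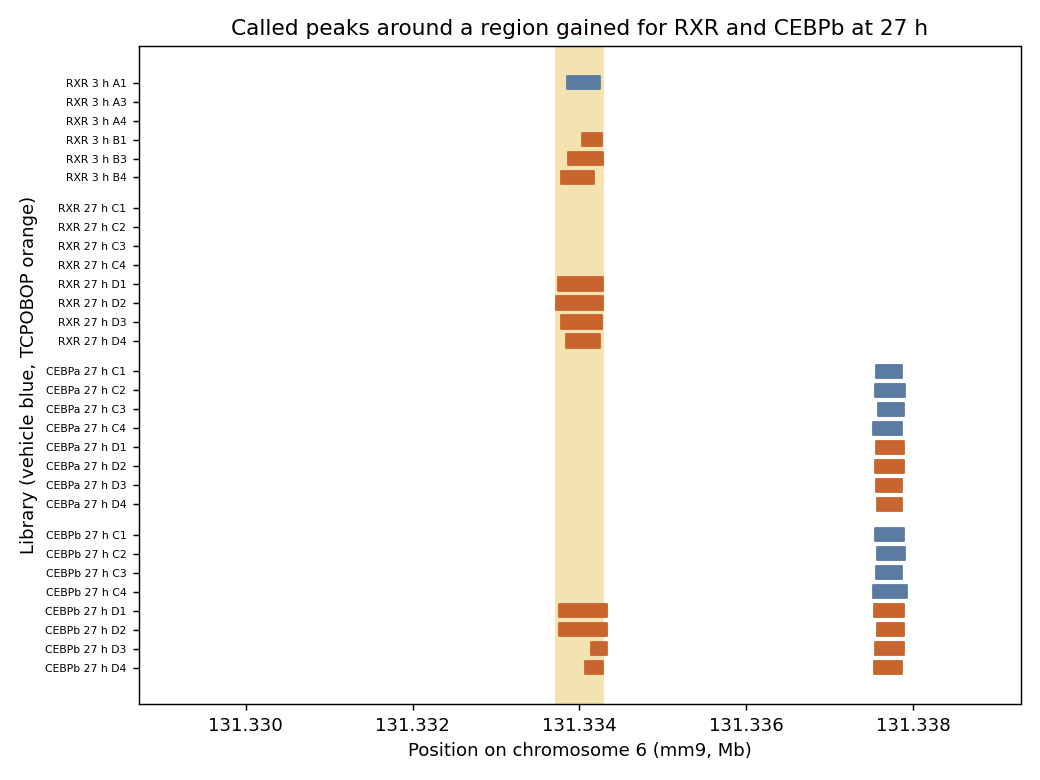
Peaks called in each library (bars) around the region on chromosome 6 gained by RXR and CEBPb at 27 h (shaded, 131333724 to 131334286), with the mm9 position in Mb on the horizontal axis and 1 library per line; vehicle is blue, TCPOBOP orange. At 27 h the shaded region holds RXR and CEBPb peaks in the 4 TCPOBOP livers and in 0 vehicle livers, while the CEBPa and CEBPb peaks to the right are present in all 8 livers.

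CEBPa and CEBPb shared 8 gained regions at 3 h, against 0.858 for independent lists (Fisher's exact test, one-sided adjusted p = 5.91e-06), and 4 with lists of equal length, against 0.48. With the full lists, none of the other joint assignments of the 6 livers gave more than 6 (exact one-sided p = 0.05, the smallest that 20 assignments allow). CEBPa and CEBPb shared 2 gained regions at 27 h, against 0.0878 for independent lists (Fisher's exact test, one-sided p = 0.00348, adjusted p = 0.00609). However, 6 of the 70 joint assignments gave as many (exact one-sided p = 0.0857). CEBPa and RXR shared 1 at that time. CEBPa gained no region at both times, and neither did CEBPb (Fisher's exact test, one-sided p = 1 for each). Independent lists would share only 0.067 and 0.341 regions, so an overlap of 0 does not show that the gains fail to recur. Of the 331 CEBPb regions gained at 27 h, 49 were among the regions called in both comparisons. When all but at most 1 TCPOBOP library sufficed, CEBPa gained 13 regions at both times, against 2.98 for independent lists (Fisher's exact test, one-sided p = 9.66e-06, unadjusted), and CEBPb 12, against 10.7. Livers were not reassigned for these looser lists, and Fisher's test treats regions as independent, so its p overstates the evidence. Under the strict rule, reassigned livers shared up to 6 CEBPa regions between times. The 0.067 expected for independent lists holds for the real lists of 179 and 23 regions. Reassigned lists held up to 786 regions at 3 h and 202 at 27 h, so the 2 numbers are not comparable. For the CEBP factors the times differ in flow cell and in age (7 weeks at 3 h, 8 weeks at 27 h), so no difference between times was tested for them beyond these overlaps of treatment results.

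At 27 h, most CEBPa peaks coincided with a CEBPb peak in the same liver. CEBPb then overlapped 89.2% ± 3.82 of CEBPa peaks in TCPOBOP livers and 81.0% ± 5.59 in vehicle livers (SD, n = 4 each), against 1.82% after moving the CEBPb peaks by 100 kb. CEBPa overlapped 47.2% ± 6.14 and 58.5% ± 7.00 of CEBPb peaks. CEBPb overlapped 41.9% ± 1.57 of RXR peaks in TCPOBOP livers and 37.1% ± 3.22 in vehicle livers, and CEBPa overlapped 27.2% ± 2.10 and 28% ± 1.38. The difference of 4.86 percentage points for CEBPb at RXR peaks had the smallest p of the 8 comparisons (exact permutation, two-sided p = 0.0286), which did not pass the correction (adjusted p = 0.152). With the lists of each pair of factors shortened to the same length, the shares were 32.9% and 31.6% for CEBPb at RXR peaks, and 71.5% in both treatments for CEBPb at CEBPa peaks. For CEBPa at CEBPb peaks they were 71.2% in TCPOBOP and 71.4% in vehicle livers. At 3 h, CEBPb overlapped 57.1% ± 6.01 of CEBPa peaks in TCPOBOP and 49.7% ± 17.0 in vehicle livers (SD, n = 3 each; exact permutation p = 0.5, two-sided).

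As a scale for these counts, the RXR vehicle livers of 27 h and of 3 h were compared with each other. They had 14 regions called only in all 4 livers of 27 h and 187 called only in all 3 livers of 3 h, out of 63464. Of the 35 assignments of these 7 libraries, 25 and 11 gave at least as many (exact one-sided p = 0.714 and 0.314). The vehicle livers of both times were of the same age and sequenced in the same lane. With 4 livers against 3, the rule asks for fewer calls at 3 h than at 27 h. The counts are therefore only a rough scale for comparisons of equal groups.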

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

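The test of reads from neighbouring libraries was written before its result was seen. Chance marks about 1 set of values in 20 as holding a distant value. Dixon's test for such a value was made on 24 sets of 4 values and marked 2. The sets are several measures of the same livers of 27 h, so they are not independent.

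The TCPOBOP liver D4 had 20396 CEBPa peaks at 27 h, far from the other 3 livers of its group, which had 28818 to 29066. In the vehicle liver C3, CEBPb overlapped 32.3% of RXR peaks at 27 h, against 38.3% to 38.9% in the other 3 vehicle livers.

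The input control of vehicle liver A38 held 1480 peaks, a signal in libraries that none of the comparisons use, against 224, 42 and 7 in the other inputs. Of these peaks, 28% overlapped regions with an RXR peak in all 6 libraries of 3 h (exact binomial 95% interval 25.7% to 30.3%), against 1.15% after the regions were moved by 100 kb. This input shared a lane with the CEBP libraries of 3 h, so reads of those libraries might have been assigned to it. That would leave regions bound by RXR alone without input peaks. Of the 8026 RXR regions with no CEBP peak at 3 h, however, 2.21% held an A38 input peak (1.90% to 2.55%), against 0.0623% after moving them (0.0202% to 0.145%), which argues against that source as the whole cause. No biological explanation was tested, and accessible chromatin or depth of this input stay open.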

How the results depend on the processing

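Equal-length lists, wider regions, midpoint windows, leaving libraries out of the RXR time effect and all settings of RXR over both times were chosen only after the data were seen. Directions and calls held with input peaks removed, with midpoint windows and with 50% of the peak or of the smaller region required. Alternatives on q-value, fold enrichment, ranking by p and summits, and those on gene lists and motifs, were not run, because the lists hold no such values and no mm9 annotation or sequence was used here. Depth is unknown, so its limits were not measured; where no cause is named, the cause was not tested.

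Gained and lost regions, in all but at most 1 library, rose by construction. RXR had 1189 and 1539 at 3 h, 539 and 670 at 27 h, so its balance turned to more lost regions at both times. CEBPa had 1305 and 2122, then 162 and 866, and CEBPb 1575 and 668, then 1468 and 309. Overlaps of gained regions became 66 (RXR 3 h and 27 h), 32 (RXR and CEBPb 27 h), 4 (RXR and CEBPa 27 h), 8 (CEBPa and CEBPb 27 h), 54 (CEBPa and CEBPb 3 h), 13 (CEBPa 3 h and 27 h) and 12 (CEBPb 3 h and 27 h), of which RXR and CEBPa at 27 h and CEBPa at both times newly passed Fisher's exact test. Counting only wider regions lowered counts by construction, with gained RXR regions at 27 h newly passing (exact p = 0.0143), to RXR 23 and 7 at 3 h, 50 and 23 at 27 h; CEBPa 20 and 55, then 6 and 20; CEBPb 66 and 10, then 62 and 3.

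With equal-length lists of the widest peaks, RXR lost 157 regions at 3 h, CEBPa gained 52 and lost 43 at 27 h, CEBPb gained 119 and lost 138 at 3 h, which turned the balance, and gained 152 and lost 75 at 27 h, RXR over both times gained 8 and lost 1, and RXR vehicle livers had 90 regions only at 27 h. Gained and lost RXR regions and gained CEBPa regions at 27 h newly passed (exact p = 0.0143, 0.0286 and 0.0286), as did the RXR counts with random peaks. Overlaps became 9 (RXR 3 h and 27 h), 2 (RXR and CEBPa 27 h), 0 (CEBPa and CEBPb 27 h), 4 (CEBPa and CEBPb 3 h) and 1 (CEBPa 3 h and 27 h), where RXR and CEBPa newly passed and CEBPa and CEBPb at 27 h no longer did. With random peaks, RXR gained 431 and lost 421 at 3 h, CEBPa gained 119 and lost 64.4 at 27 h, CEBPb lost 313 at 3 h and gained 173 and lost 96.4 at 27 h. The similarity difference reversed for CEBPa (0.00113) and CEBPb (0.00122) at 3 h and passed for CEBPa at 27 h (0.00532). Differences in shared peaks reversed for CEBPb by CEBPa at 3 h (0.0956), RXR by CEBPa (0.197), CEBPa by CEBPb (-0.0402) and CEBPb by RXR (1.22) at 27 h, and RXR by CEBPb no longer passed (1.24).

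Liver numbers did not pair the livers (correlations -0.0025 to 0.053). Under the replicate block, the similarity differences of RXR (0.0142) and CEBPb (0.0119) at 27 h had an exact p of 0.125, and the 331 gained CEBPb regions at 27 h had an exact p of 0.0625. These are the smallest p-values that 4 pairs allow for the 2 measures, and no other call changed under the block.

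Leave-one-out ranges, where counts rise by construction with fewer libraries: gained RXR 211 to 1720 (3 h), 194 to 370 (27 h) and 16 to 43 (both times), CEBPa 265 to 727 and 36 to 99, CEBPb 301 to 963 and 459 to 747; lost RXR 104 to 1293, 171 to 367 and 0 to 2, CEBPa 523 to 1409 and 173 to 431, CEBPb 69 to 457 and 62 to 140; vehicle RXR 20 to 343 only at 27 h and 222 to 1807 only at 3 h. Log2 peak number: RXR -0.18 to 0.44 and -0.18 to 0.0044, CEBPa -0.22 to 0.0515 and -0.35 to -0.14, CEBPb 0.05 to 0.51 and 0.14 to 0.24, RXR time effect -0.54 to 0.0838. Similarity: RXR -0.0388 to 0.0311 and 0.0113 to 0.0161, CEBPa -0.00622 to 0.00407 and 0.000427 to 0.0170, CEBPb -0.0135 to 0.00779 and 0.00534 to 0.0175. The similarity call was lost in 5 of 8 cases for RXR and 4 of 8 for CEBPb at 27 h, and CEBPa at 27 h passed in 1 of 8, as did the peak numbers of CEBPa and CEBPb at 27 h.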

Other observations

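The tests of fragment length, of other splits for the 6 treatment comparisons and of the CEBPb to CEBPa ratio were chosen only after the result was seen, and equal-length lists of the widest peaks were an alternative added after the lists were seen.

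At 27 h, regions called in all 4 livers of a treatment fell into classes by factor. In vehicle livers, 4650 of 37667 such regions had all 3 factors, 11558 had both CEBP factors without RXR, 10885 had RXR alone, 7986 CEBPb alone and 847 CEBPa alone. In TCPOBOP livers the numbers were 4148, 10237, 9308, 13590 and 164 of 40082 regions. RXR with CEBPb but without CEBPa was found at 1699 and 2626 regions. These numbers move with the length of the lists, and the difference between treatments was not tested.

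The ratio of CEBPb to CEBPa peaks within the same liver had a geometric mean of 1.90 in TCPOBOP and 1.39 in vehicle livers at 27 h (exact permutation of the log2 ratio, n = 4 each, two-sided p = 0.0571), and of 0.719 and 0.561 at 3 h (n = 3 each, exact p = 0.5). All 42 immunoprecipitated libraries had their highest density of autosomal peaks on chromosome 19. The density on the X chromosome was 0.169 of the autosomal one for RXR (SD 0.0192 over 14 libraries), 0.221 for CEBPa (SD 0.0181) and 0.219 for CEBPb (SD 0.0242). The mice were male, and the ratio was not corrected for the single X chromosome. Among RXR vehicle livers of 3 h it was 0.135 in A3, with 22117 peaks, and 0.213 in A1, with 52727.

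The region on chromosome 3 at 113022802 to 113023178 was gained by all 3 factors at 27 h. The region on chromosome 12 at 14216580 to 14217028 was gained by both CEBP factors at 27 h and had RXR peaks in every library of both times. These were the 2 regions shared by the gained CEBPa and CEBPb lists of 27 h. With equal-length lists of the widest peaks those lists shared 0 regions. With the full lists, 6 of the 70 joint assignments of the livers gave as many.

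CEBPb gained many more regions at 27 h than it lost, and a longer list in the TCPOBOP livers might produce such a difference. With lists of equal length the lead shrank from 331 against 34 to 152 against 75 regions, so list length can account for part of it. The 152 gained regions still exceeded the 91 of the highest other assignment, which argues against length as the whole cause. A different fragment length is also not in favour, since the shortest CEBPb peak differed by -0.5 bp on average between TCPOBOP and vehicle lists. That the shortest peak follows the fragment length is an assumption that was not checked. For RXR at 27 h the shortest peaks were 189 to 195 bp in TCPOBOP and 186 to 189 bp in vehicle lists. Fragment length was not tested as a cause for RXR. A change of CEBPb binding after TCPOBOP is a hypothesis that stays open beside unequal enrichment of the libraries.

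RXR regions gained at 27 h were called more often in the TCPOBOP than in the vehicle livers of 3 h, which are other animals. Shorter vehicle lists at 3 h may give such a difference, and the vehicle livers did vary from 22117 to 52727 peaks. With all 3 h lists shortened to 22117 peaks, the excess over control regions was 18.2 percentage points (bootstrap 95% interval over regions 13.5 to 23.1), which argues against list length as the whole cause. The interval covers the spread between regions and not between animals. An early RXR gain at these sites is a hypothesis, which 3 livers against 3 are too few to settle.

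Counts of gained plus lost regions were set against other splits of the same libraries. Only the real split was as large for RXR at 27 h (298 regions, highest other 185; 1 of 35 splits), for CEBPb at 27 h (365, highest other 238; 1 of 35) and for RXR at both times (15, highest other 11; 1 of 100 drawn splits). Each of these shares is under 0.05 for a single test taken alone, and 1 of 35 is the smallest share that 35 splits allow. Such a share does not exclude chance. The shares are not corrected over the comparisons, and those of the treatment comparisons were chosen after the result was seen. The correction over the 12 gained and lost counts, a family chosen after the data were seen, could not be passed (smallest possible adjusted exact p 0.0571). It therefore decides neither way. A correction over fewer counts was not made, and chance stays open over the comparisons together. The comparison of RXR at both times was added after the data were seen and counts the same 15 regions as the overlap of its gained lists, so it is no separate evidence. Among all 700 splits the highest other sum was 13, equal-length lists left 8 gained regions and 1 lost, and chance stays open there too. Chance also stays open for CEBPa at 27 h (23 gained and 131 lost, highest other sum 210; 4 of 35 splits) and for RXR in vehicle livers of 27 h against 3 h (201, highest other 1250; 18 of 35). With 3 livers against 3 the 10 splits are too few: RXR at 3 h gave 256 (highest other 1434; 7 splits as large), CEBPa 497 (834; 4 splits) and CEBPb 271 (765; 7 splits). The split with most RXR regions at 3 h set livers B1, B4 and A1, with 43070 peaks on average, against the others, with 29565, and the one among RXR vehicle livers set C4, A1 and A4, with 40578, against 26911. These splits follow list length, a structure of the samples other than treatment.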
